A study of Homo sapiens with 6 samples.

How the data were processed

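Total RNA of A549 cells was sequenced in 6 libraries, 3 with an empty piggyBac vector and 3 with piggyBac overexpression of LOC401312. Samples were grouped by their titles. The genotype labels of LOC401312 replicates 2 and 3 name other loci, LOC401313 and LOC401314, against their titles and the design text, and the STEAP1B entry that holds LOC401312 was as high in both as in replicate 1. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

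The authors deposited one table of 38170 annotated features with raw counts and FPKM (fragment counts scaled for transcript length and library total) for each library, per the file headers. The counts are whole numbers, 1 column per library, with no pooling and no normalization, as deposited by the authors. The FPKM values, scaled for length and library total by the authors, are given to a pair of decimals, and how length and total were defined is not given in the sources used here. Reads were processed with cutadapt 1.9 and FastQC and the genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping antisense genes could not be told apart. Every feature had a gene identifier, and 4900 had 0 counts in all libraries. A column of gene identifiers of another database in the same table was not used here.

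Library totals were 60971105 to 73994619 counts, and the biological coefficient of variation was 17%. Within each group, every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 13.68 to 22.86 over features with a mean of at least 50 counts; Spearman correlation across genes 0.9917 to 0.9941), so each was counted as 1 replicate. Floors and intervals cover counting error only: a group with 0 counts was taken at a floor of 3 counts over the group, and ratios of counts carry exact binomial intervals at 95%.

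The planned test was limma on log2(FPKM + 0.1), because FPKM was expected. Since the table also held raw counts, the replacement named in the plan was used: edgeR 4.0.16 quasi-likelihood test with TMM scaling and filterByExpr, R 4.3.3, group as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes are from this edgeR fit unless another tool is named, and standard errors are the log2 change divided by the square root of the F statistic. CPM values use the TMM-adjusted library sizes. LOC401312 was located by its RefSeq span, which matched 1 transcript of the 8 in the STEAP1B entry.

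The 26 gene lists, the rule for naming genes and the first set of other settings were fixed before the data were examined. The rule named LOC401312 and CPS1, the 10 features with the largest rise and the 10 with the largest fall in log2(FPKM + 0.1) among those past the threshold, with a mean FPKM of at least 1 in the higher group, no overlap between groups and no clone-type or pseudogene name, every measured urea cycle gene, and up to 3 past the threshold per list with the smallest p (or 2 where none passed). Some genes that this rule gives are not reported here. Other genes named were chosen after their values were seen. The lists cover the urea cycle, pyrimidine and purine synthesis, non-homologous end joining, homologous recombination, base excision repair, ATM and ATR signalling, p53 targets, G1/S, G2/M, apoptosis, NRF2 targets, interferon-stimulated genes, NF-kB targets, hypoxia and glycolysis, cholesterol synthesis, ATF4 and the unfolded protein response, epithelial junctions, mesenchymal and matrix genes, immediate early genes, liver, alveolar, haematopoietic, fibroblast and endothelial, and kidney and cervical cell line markers, and mitochondrially encoded and ribosomal protein genes.

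Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation and with fry. By camera 11 were called, with an estimated correlation 1, and by fry, which asks whether a list's genes move one way on balance, 12, the mesenchymal and the kidney and cervical cell line lists among them, which camera did not call. The ribosomal protein list, called by camera, was not called by fry (adjusted p = 0.203). Chromosomes (23, genes with a mean of at least 4 CPM) were compared with camera in the same way.

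The settings in that first set were DESeq2 1.42.0, other filters, the replicate number as a block, each library left out in turn, stricter thresholds, and limma on FPKM with pseudocounts of 1 and 0.01, other filters, other scalings, no trend or a robust fit. Added after the data were seen were limma on log2(FPKM + 0.1), the first test of the plan, kept for comparison, RLE, total-count and median scaling of counts, a robust edgeR fit, removal of a length trend (loess span 0.3, with length taken from the ratio of counts to FPKM) or of chromosome medians, a fit without LOC401312 replicates 2 and 3, the chromosome comparison, and camera over 301 KEGG and 1348 Reactome terms of 10 to 200 genes given in the deposited table. There were 31 settings besides the one reported. Limma on FPKM used features with a mean FPKM of at least 0.5 unless another filter is named.

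The steps were tested on simulated data for this comparison, with counts drawn for 19078 genes from these libraries. The edgeR test recovered 28% of 100 genes changed 1.3-fold and 88% of 100 changed 2-fold, with 18 false calls among 18852 unchanged genes; DESeq2 recovered 48% and 93%. Changes near 1.3-fold that were not called are therefore not shown to be absent. The changed genes all had a mean of at least 100 counts, so recovery of genes with fewer counts was not measured. A planted list was found, but all its members were raised 1.3-fold, so finding weaker or mixed lists was not tested. In the same simulation 0 other lists and 0 chromosomes were called. Each gene was drawn independently of the others. These 0 calls therefore do not show how the list and chromosome tests behave where genes vary together, as in the real libraries.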

Results

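RNA was sequenced from A549 cells, a human lung adenocarcinoma line, that carried either LOC401312, a long non-coding RNA, or an empty vector. Both were introduced with piggyBac, a transposon system that inserts DNA into the genome. There were 3 libraries per group. The libraries held 73994619, 60971105 and 62192228 counts for vector and 70202062, 67894491 and 65823845 counts for LOC401312. Of 38170 annotated features, 19620 had enough counts to be tested. Fold changes are LOC401312 over vector, on the log2 scale, with standard errors (SE) from edgeR's quasi-likelihood fit.

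The first comparison asked whether the introduced transcript was present and whether CPS1, the gene named in the title of the series, changed with it. LOC401312 lies on chromosome 7 at 22649960 to 22665533 in GRCh38. It has no entry under its own name, and its span is that of a 5-exon transcript annotated to STEAP1B, on the minus strand, so its reads were read from the STEAP1B entry (ENSG00000105889; chromosome 7, 22419444 to 22665502). That entry held 9, 11 and 23 counts in the vector libraries and 94628, 92527 and 90297 counts in the LOC401312 libraries. In CPM, counts scaled to the same library total, this was 0.226 ± 0.132 (SD, n = 3) against 1350 ± 7.6 (SD, n = 3), a rise of 12.57 (SE 0.14, adjusted p = 1.63e-11). The entry joins 8 transcripts, so LOC401312 and the other STEAP1B transcripts could not be counted apart.

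CPS1 (ENSG00000021826; chromosome 2, 210477682 to 210679107, plus strand), the mitochondrial enzyme that makes carbamoyl phosphate from ammonia in the first step of the urea cycle, rose 2.11-fold. Its level was 58.0 ± 1.4 CPM (SD, n = 3) in vector and 123 ± 2.83 CPM (SD, n = 3) in LOC401312, a log2 change of 1.08 (SE 0.04, adjusted p = 1.04e-06). Every LOC401312 library lay above every vector library for both entries. The exact two-sided permutation test gave p = 0.1 for each, the smallest value that 20 arrangements of 3 against 3 allow.

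**Figure D1:**
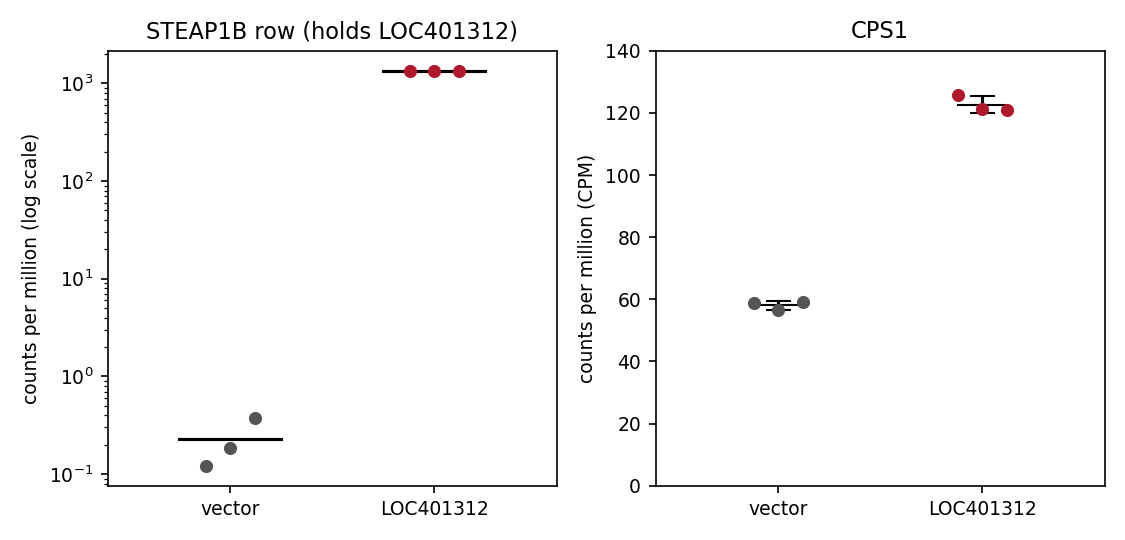
CPM in each library for the STEAP1B entry, which holds the LOC401312 reads (left, log axis, line at the mean), and for CPS1 (right, linear axis, line at the mean with SD bars), in vector (grey) and LOC401312 (red), n = 3 each. CPS1 lay between 56.4 and 59.0 CPM in vector and between 121 and 126 CPM in LOC401312.

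Beyond these, the rises with the largest change in deposited expression value included membrane transporters and secreted proteins. SLC6A14, an amino acid transporter, rose by 2.54 (SE 0.12, adjusted p = 4.98e-06), from 7.6 ± 1.41 to 44.3 ± 2.36 CPM (SD, n = 3 each). SLC6A15, another amino acid transporter, rose by 1.9 (SE 0.07, adjusted p = 6.77e-07), and the protease inhibitor SERPINB3 by 2.73 (SE 0.23). HSD11B1, which regenerates active glucocorticoid, rose by 2.26, HYAL1, a hyaluronidase, by 1.72, PIP by 1.67 and PF4 by 1.82. KISS1 (6.29, SE 1.16) and CGB8 (4.80, SE 0.90), both abundant in placenta, also passed the threshold. Their CPM in LOC401312 varied widely, 1.77 ± 1.54 and 5.56 ± 4.6 (SD, n = 3 each), because replicates 2 and 3 held more of both than replicate 1. CGB8 has near-identical copies among the chorionic gonadotropin genes, so its own count is uncertain.

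The largest falls included the keratin KRT13, which fell by 7.42 (SE 0.59, adjusted p = 8.12e-05), from 4.48 ± 0.219 to 0.0236 ± 0.0409 CPM (SD, n = 3 each). CDKN2A, which A549 cells are known to have deleted, was counted in every vector library and in no LOC401312 library, and the origin of the vector counts of both genes was not tested. ADIRF fell by 4.67, with 121, 92 and 44 counts in vector and 0, 3 and 7 in LOC401312, and the origin of its vector counts was not tested either. INHBB, a subunit of activin B and inhibin B, fell by 1.72 (SE 0.08, adjusted p = 2.18e-06), from 61.4 ± 5.92 to 18.6 ± 0.874 CPM. The most abundant gene of this group was CPLX2, a regulator of vesicle fusion, which fell by 1.45 (SE 0.04, adjusted p = 1.38e-07), from 1361 ± 65.6 to 497 ± 17.6 CPM. PTX3, a soluble pattern recognition protein, fell by 1.92, PADI2, which converts arginine to citrulline in proteins, by 1.61, and PSCA by 1.87. The readthrough entries POC1B-GALNT4 (-3.96), PMF1-BGLAP (-1.94) and HNRNPUL2-BSCL2 (-1.38) share exons with their neighbours and are uncertain. Leaving out 1 library ended the calls of KISS1 (without vector replicate 3, adjusted p = 0.0501), CGB8 (vector replicate 2 or 3, up to 0.0606), PF4 (any but vector replicate 1, up to 0.156), PSCA (vector replicate 2 or LOC401312 replicate 2 or 3, up to 0.0776) and POC1B-GALNT4 (LOC401312 replicate 1 or 2, up to 0.0701).

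In all, 1710 features passed an adjusted p of 0.05, 8.72% of those tested, with 811 higher and 899 lower in LOC401312. The median size of these changes was 0.36, and 135 rose and 66 fell by at least 1. The split depended on scaling. With limma on the deposited FPKM values, 2014 were higher and 348 lower (85.3% higher, against 47.4% here), because those values were shifted. The median over genes with a mean FPKM of at least 5 was 0.109 in them, and this is the shift given below. After rescaling to one sum the split was 1175 to 511 (69.7% higher). Relative to the counts above, the number higher or lower moved over 1.5 times without vector replicate 2 (580 lower), vector replicate 3 (421 and 493), LOC401312 replicate 1 (472 and 546), 2 (393 and 439) or 3 (429 and 530), and to 108 and 118 without LOC401312 replicates 2 and 3, which carry placental transcripts.

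The genes of chromosome 2 were lower together, although CPS1 lies there. Of 780 chromosome 2 genes with a mean of at least 4 CPM, 342 fell, 13 rose and 90.1% had a negative log2 change. Their median was -0.233, a 0.851-fold level (camera adjusted p = 1.43e-36; adjusted p = 0.0014 with an estimated correlation). All 13 segments of 20 Mb had a negative median, from -0.32 to -0.15. Genes of chromosome 12 were higher, with 110 of 642 called higher, 8 lower and a median of 0.117 (adjusted p = 1.22e-11; 0.00101 with an estimated correlation). Chromosome 9 had a median of -0.086, with 67 of 494 genes called lower and 12 higher (adjusted p = 3.55e-05; adjusted p = 0.0697 with an estimated correlation). The medians of the other 20 chromosomes lay between -0.012 and 0.024. Among genes with a mean FPKM of at least 5, the medians of chromosomes 2, 9 and 12 were -0.238, -0.106 and 0.094 in the counts. In the deposited FPKM values, whose shift over such genes was 0.109, they were -0.109, 0.021 and 0.217. That of chromosome 9 thus turned positive but stayed below the shift. Chromosome 2 held 348 of the 899 falls, 38.7% of them against 6.5% of the tested features (Fisher's exact test, two-sided, p = 6.23e-187; odds ratio 12, across genes, which are not independent replicates). Outside chromosomes 2, 9 and 12 there were 661 rises and 472 falls. With each chromosome's median removed from each library, CPS1 had a log2 change of 1.3, and 642 features were higher and 570 lower.

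**Figure D2:**
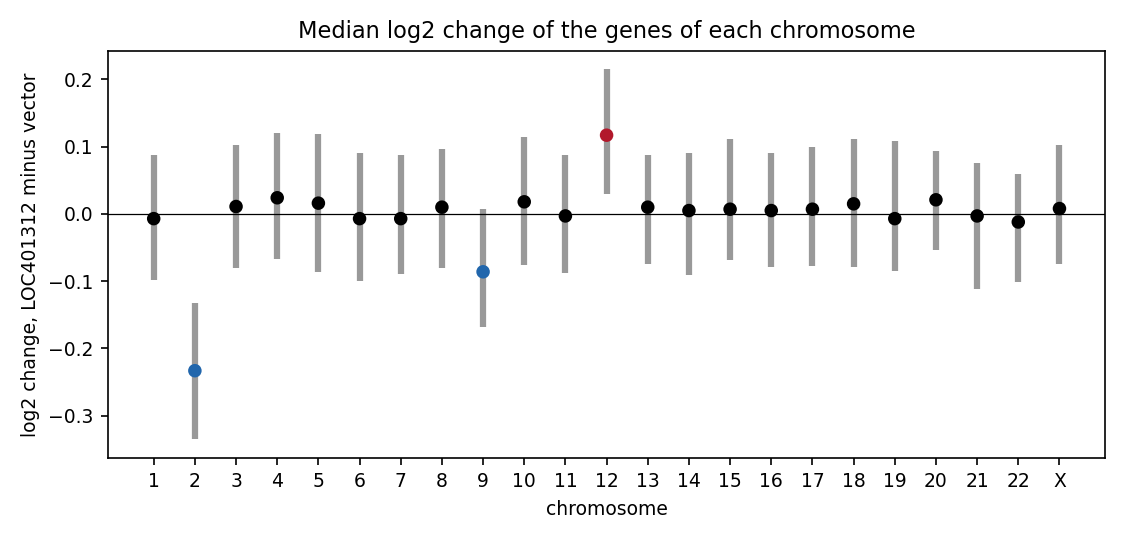
Median log2 change (points) and interquartile range (bars) of the genes of each chromosome with a mean of at least 4 CPM, LOC401312 minus vector. Chromosome 2 lay at -0.233, chromosome 9 at -0.086 and chromosome 12 at 0.117, and the other 20 chromosomes between -0.012 and 0.024. Among genes with a mean FPKM of at least 5, chromosome 9 lay at -0.106 in the counts. In the deposited FPKM values of such genes it lay at 0.021, with a shift of 0.109.

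The next comparisons took 26 gene lists fixed before the data were examined. Among 11 measured genes of the urea cycle and ammonia handling, 2 rose, CPS1 among them, and 9 did not pass the test. CPS1 rose by 1.08 (SE 0.04). Those that did not pass had log2 changes of 0.07 for ASS1, -0.03 for ASL, 0.21 for ARG2, 0.13 for NAGS, -0.12 for SLC25A15, 0.02 for SLC25A13, 0.09 for GLUD1, -0.11 for GLUD2 and 0.06 for GLUL, with adjusted p of 0.216 or more. Adjusted over the list alone, the same number, 2, were higher. CPS1 had the largest rise of the measured members, and the list was not tested without it. The list's median was 0.07 (camera adjusted p = 0.00477, or 0.153 with an estimated correlation). With limma on the deposited FPKM values it was 0.18 and the call was lost (camera adjusted p = 0.165). The shift of those values, over genes with a mean FPKM of at least 5, was 0.109.

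Of 22 genes of de novo pyrimidine and purine synthesis, 3 fell and none rose, and 4 fell adjusted over the list alone. ATIC, an enzyme of the last steps of purine synthesis, fell by 0.43 (SE 0.04, adjusted p = 0.000145), CAD, which makes the carbamoyl phosphate used for pyrimidines, by 0.27 (SE 0.05, adjusted p = 0.0115) and RRM2, a ribonucleotide reductase subunit, by 0.17 (SE 0.04, adjusted p = 0.0269). All 3 lie on chromosome 2. With chromosome medians removed, ATIC was at -0.21 (adjusted p = 0.0104), CAD at -0.05 (0.651) and RRM2 at 0.05 (0.482). The list's median was -0.08 (camera adjusted p = 0.00934; adjusted p = 0.153 with an estimated correlation), and in the deposited FPKM values it was 0.05, below their shift of 0.109. With chromosome medians removed the list's median was -0.08, and the list stayed called (camera adjusted p = 0.0324). The list's call was lost among features with a mean FPKM of at least 5 (adjusted p = 0.143). RRM2 lost its call on leaving out any library but vector replicate 1 (adjusted p up to 0.102), and CAD without LOC401312 replicate 2 (0.0706).

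No list of DNA repair genes was called, a group of interest because the title of the series concerns radiosensitivity; no library was labelled as irradiated. Of 19 non-homologous end joining genes, XRCC5, which encodes Ku80, fell by 0.36 (SE 0.04, adjusted p = 0.000274) and NHEJ1 by 0.32 (SE 0.08, adjusted p = 0.0273), and 17 did not pass, with 2 falling adjusted over the list alone. Both lie on chromosome 2, and with its median removed they were at -0.15 (adjusted p = 0.031) and -0.10 (0.498). Of 28 homologous recombination genes, FANCD2 (-0.27), RPA3 (-0.27) and RAD54B (-0.35) fell, and adjusted over the list alone 2 rose and 4 fell. Of 21 base excision and single-strand break repair genes, UNG rose by 0.15 (SE 0.04, adjusted p = 0.0431), and 0 passed adjusted over the list alone. UNG lies on chromosome 12 and was at 0.02 (adjusted p = 0.806) with that chromosome's median removed. None of 22 ATM and ATR checkpoint genes passed either way, with ATR at 0.20 (adjusted p = 0.0613) and TOPBP1 at -0.15 (0.152). The lists' medians were 0, -0.05, -0.08 and -0.08 and their camera adjusted p 0.384, 0.384, 0.387 and 0.305; in the deposited FPKM values the medians were 0.13, 0.08, 0.05 and 0.05. Leaving out 1 library ended the calls of UNG (any, up to 0.17), NHEJ1 (any but LOC401312 replicate 1, up to 0.106), RAD54B (any but vector replicate 2, up to 0.126), RPA3 (any but vector replicate 1, up to 0.0802) and FANCD2 (LOC401312 replicate 2 or 3, up to 0.0806); ATR passed without vector replicate 1 (0.00752).

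Among 29 p53 targets, 2 rose and 3 fell, and adjusted over the list alone 2 rose and 4 fell. GDF15, a stress-induced cytokine, fell by 0.49 (SE 0.07, adjusted p = 0.00238), FDXR by 0.32 and RPS27L by 0.30. Of 28 apoptosis regulators, 2 rose and 3 fell, by either adjustment. BIRC3, an inhibitor of apoptosis that is also a target of NF-kB, rose by 0.44 (SE 0.06, adjusted p = 0.00183). The proapoptotic BCL2L11, on chromosome 2, fell by 0.44 (SE 0.07, adjusted p = 0.00309), and was at -0.23 (0.0738) with that chromosome's median removed. The antiapoptotic BCL2L1 fell by 0.23 (SE 0.04, adjusted p = 0.00615). Neither list was called, with medians of -0.02 and 0.02 and camera adjusted p of 0.387 and 0.688; the p53 median was 0.01 with total-count scaling and 0.11 in the deposited FPKM values. RPS27L lost its call without vector replicate 3 (adjusted p = 0.0531).

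Of 26 genes of G2/M and mitosis, 5 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose. The centromeric histone CENPA fell by 0.55 (SE 0.08, adjusted p = 0.00328), from 26.0 ± 1.19 to 17.8 ± 1.58 CPM (SD, n = 3 each), the checkpoint kinase BUB1 by 0.35 (SE 0.05) and cyclin B1, CCNB1, by 0.17 (SE 0.04). CENPA and BUB1 lie on chromosome 2, and with its median removed were at -0.33 (adjusted p = 0.0473) and -0.13 (0.141). The list's median was -0.10 (camera adjusted p = 0.0123, or 0.275 with an estimated correlation). In the deposited FPKM values it was 0.03, below their shift of 0.109. With chromosome medians removed it was -0.13, and the list stayed called (camera adjusted p = 0.00205). The call was lost among features with a mean FPKM of at least 5 (adjusted p = 0.123). Of 26 genes of G1/S and DNA replication, the helicase subunit MCM6, on chromosome 2, fell by 0.28 (SE 0.04, adjusted p = 0.0025) and POLE, on chromosome 12, rose by 0.19 (SE 0.04, adjusted p = 0.0277), 1 each also when adjusted over the list alone. With chromosome medians removed they were at -0.06 (0.471) and 0.06 (0.476). That list's median was -0.04 (camera adjusted p = 0.27; 0.08 in the deposited FPKM values). CCNB1 lost its call without any library but vector replicate 1 (adjusted p up to 0.108), and POLE without vector replicate 3 or any LOC401312 library (up to 0.122).

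The list NF-kB and inflammatory cytokines was higher as a set, though not in every member. Of 23 measured, 10 rose and none fell, and 12 rose adjusted over the list alone. The other 13 did not pass over all genes, and 5 members had a negative log2 change. The neutrophil chemokine CXCL5 rose by 0.73 (SE 0.04, adjusted p = 1.26e-05), from 279 ± 11.04 to 463 ± 13.1 CPM (SD, n = 3 each). CXCL1 rose by 0.65 (SE 0.05, adjusted p = 6.47e-05), and TNFAIP3, a feedback inhibitor of NF-kB, by 0.69 (SE 0.06, adjusted p = 8.12e-05). The list's median was 0.30 (camera adjusted p = 7.43e-15). This was the 1 list of 26 that was also called with an estimated correlation (adjusted p = 0.0224), and its median was positive under every scaling tried. It was 0.453 among features with a mean FPKM of at least 5, 0.46 without vector replicate 1, 0.556 with limma on the deposited FPKM values and between 0.399 and 0.565 in the limma settings. Without LOC401312 replicates 2 and 3 its median was 0.36 (adjusted p = 2.02e-11).

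Targets of NRF2, the transcription factor of the oxidative stress response, were lower. A549 cells carry a KEAP1 mutation that keeps NRF2 active. Of 28 targets, 18 fell and 1 rose, and adjusted over the list alone 19 fell and 2 rose. HMOX1, which degrades haem, fell by 0.90 (SE 0.05, adjusted p = 1.47e-05), from 337 ± 23.9 to 180 ± 4.99 CPM (SD, n = 3 each). The peroxidase GPX2 fell by 0.88 (SE 0.07, adjusted p = 7.11e-05) and the reductase AKR1B10 by 0.45 (SE 0.03, adjusted p = 5.87e-05), from 2175 ± 62.2 to 1587 ± 34.6 CPM. The list's median was -0.24 (camera adjusted p = 1.17e-17, or 0.153 with an estimated correlation). It was negative under every scaling tried, and was -0.11 in the deposited FPKM values. The shift of those values, over genes with a mean FPKM of at least 5, was 0.109. With limma on the deposited FPKM values camera called 4 lists, those of NF-kB targets, NRF2 targets, ribosomal proteins and fibroblast and endothelial genes. The ribosomal protein genes, a list on RNA quality, were also called lower by camera (median -0.12), but not by fry. The library medians of the NRF2 and ribosomal lists had the same order within each group. For NRF2 targets they were 0.054, 0.166 and 0.133 in vector and -0.094, -0.104 and -0.135 in LOC401312. For ribosomal proteins they were -0.044, 0.133 and 0.082 in vector and 0.03, -0.068 and -0.145 in LOC401312. The mitochondrially encoded genes were lower too (median -0.05), but their median was 0 with a length trend removed. The AKR1C genes of the list are close paralogs, and their separate counts are uncertain.

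**Figure D3:**
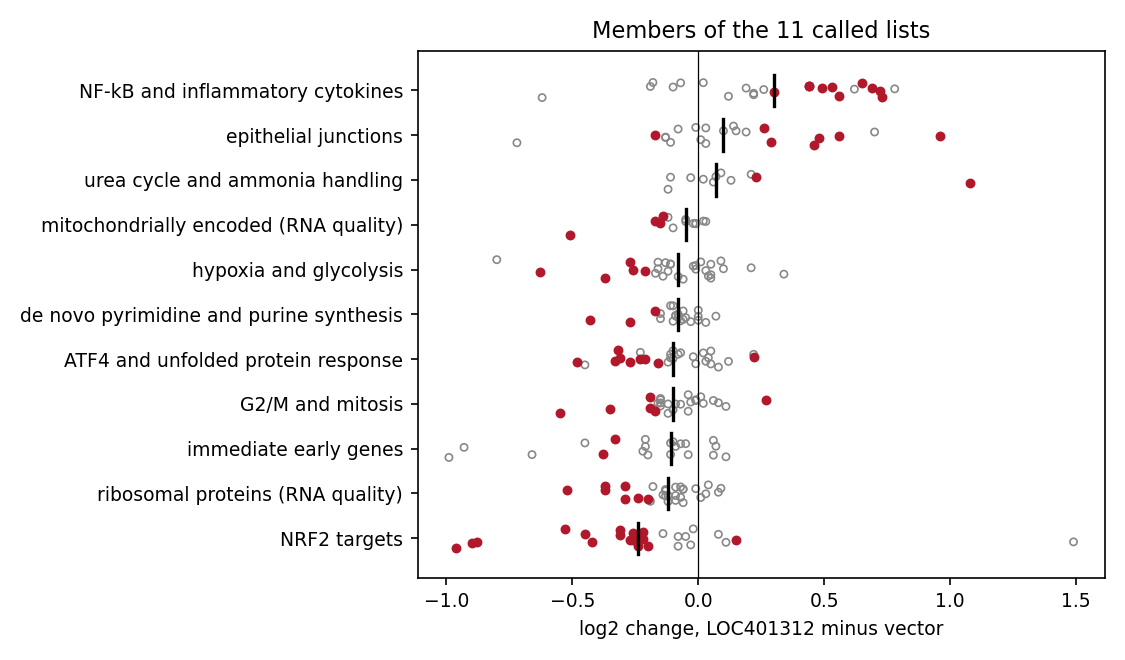
Log2 change of each member of the 11 lists called by camera, LOC401312 minus vector, with members past an adjusted p of 0.05 filled (red), the others open, and the median as a bar. NF-kB targets had a median of 0.30 and NRF2 targets -0.24. In the deposited FPKM values the medians of the nucleotide synthesis, G2/M, hypoxia, ATF4, immediate early and mitochondrial lists were above 0 and that of the ribosomal list was 0. The shift of those values, over genes with a mean FPKM of at least 5, was 0.109.

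Of 29 genes of hypoxia and glycolysis, 5 fell and none rose, and adjusted over the list alone 9 fell and 1 rose. Carbonic anhydrase CA12 fell by 0.63 (SE 0.03, adjusted p = 8.4e-06), from 824 ± 20.6 to 532.5 ± 4.69 CPM (SD, n = 3 each), PFKFB3, which makes an activator of glycolysis, by 0.37 (SE 0.04) and the phosphofructokinase PFKP by 0.27 (SE 0.05). The median was -0.08 (camera adjusted p = 0.00934; adjusted p = 0.516 with an estimated correlation). Of 28 genes of ATF4 and the unfolded protein response, 8 fell and 1 rose, by either adjustment. Those named were enzymes of amino acid and one-carbon synthesis: ASNS fell by 0.33 (SE 0.05, adjusted p = 0.00419), PSAT1, on chromosome 9, by 0.27 (SE 0.04, adjusted p = 0.00243) and MTHFD2, on chromosome 2, by 0.31 (SE 0.04, adjusted p = 0.00228). With chromosome medians removed, PSAT1 was at -0.19 (0.0184) and MTHFD2 at -0.09 (0.248). The median was -0.10 (camera adjusted p = 0.00934; adjusted p = 0.153 with an estimated correlation). In the deposited FPKM values the medians of the hypoxia and ATF4 lists were 0.06 and 0.03, below the shift of 0.109. With chromosome medians removed they were -0.09 and -0.1, and both lists stayed called (camera adjusted p = 0.000279 and 0.00346). The hypoxia list was not called without LOC401312 replicates 2 and 3 (adjusted p = 0.0576), nor the ATF4 list among features with a mean FPKM of at least 5 (0.18).

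Of 21 immediate early genes, the nuclear receptor NR4A1 fell by 0.38 (SE 0.07, adjusted p = 0.01) and the phosphatase DUSP5 by 0.33 (SE 0.06, adjusted p = 0.0112), and 3 fell adjusted over the list alone. The median was -0.11 (camera adjusted p = 0.0401; adjusted p = 0.256 with an estimated correlation), and 0.03 in the deposited FPKM values, below their shift of 0.109. Among 26 genes of cholesterol and fatty acid synthesis 2 rose and 2 fell, by either adjustment. The sterol carrier STARD4 rose by 0.51 (SE 0.06, adjusted p = 0.000554) and MVD rose by 0.28 (median 0, camera adjusted p = 0.688; 0.12 in the deposited FPKM values). Of 30 interferon-stimulated genes 3 rose and 2 fell, and adjusted over the list alone 3 rose and 3 fell. SAMD9 rose by 0.65 (SE 0.09, adjusted p = 0.00238) and IFIT1 fell by 0.63 (SE 0.10, adjusted p = 0.00377). The interferon list's median was 0.03 and its mean -0.01, with a camera direction of up (adjusted p = 0.799), and its median was -0.01 with chromosome medians removed. The immediate early list lost its call without vector replicate 2 (camera adjusted p = 0.076) or LOC401312 replicate 1 (0.0937). It also lost it with total-count scaling (0.0563), with a length trend removed (0.104) and among features with a mean FPKM of at least 5 (0.662). Without LOC401312 replicates 2 and 3 its median was -0.15. Leaving out 1 library also ended the calls of NR4A1 (vector replicate 3, 0.0521), DUSP5 (vector replicate 2 or 3 or LOC401312 replicate 1 or 3, up to 0.0615) and MVD (LOC401312 replicate 1 or 2, up to 0.0924).

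Of 21 genes of epithelial junctions, 6 rose and 1 fell, and adjusted over the list alone 7 rose and 2 fell. E-cadherin, CDH1, rose by 0.48 (SE 0.04, adjusted p = 0.000131), from 76.5 ± 1.77 to 107 ± 2.62 CPM (SD, n = 3 each). LAMB3, a laminin chain of epithelial basement membranes, rose by 0.56 (SE 0.06, adjusted p = 0.000254) and the desmosomal protein DSP by 0.29 (SE 0.04, adjusted p = 0.00157). The median was 0.10 (camera adjusted p = 0.00934; adjusted p = 0.275 with an estimated correlation). Of 32 mesenchymal and extracellular matrix genes, 12 rose and 6 fell, and adjusted over the list alone 14 rose and 9 fell. The fibrillar collagen COL5A1 rose by 0.81 (SE 0.04, adjusted p = 8.4e-06), while the type I collagen genes COL1A1 and COL1A2 fell by 0.95 (SE 0.09, adjusted p = 0.000149) and 1.44 (SE 0.13, adjusted p = 0.000182). This list was not called by camera (median 0.05, mean -0.16, camera direction up, adjusted p = 0.249; adjusted p = 0.433 with an estimated correlation) with all tested features. It was called higher among features with a mean FPKM of at least 5, with edgeR (median 0.152, adjusted p = 0.000266) and with limma (0.259, adjusted p = 0.0141), and by fry (adjusted p = 0.0306). The epithelial list lost its call without vector replicate 1 (adjusted p = 0.0712), and with chromosome medians removed its median was 0.01 (adjusted p = 0.0363). With limma on the deposited FPKM values its median was 0.20 and the call was lost (adjusted p = 0.165).

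None of the 5 lists of other cell types was called by camera in the edgeR fit of the counts of all 6 libraries, and fry called the kidney and cervical cell line list lower (adjusted p = 0.0306). Among 11 liver secreted proteins 3 rose and 2 fell, and adjusted over the list alone 3 rose and 3 fell: FGL1 rose by 0.71 (SE 0.10), VTN rose by 0.50 (SE 0.08) and AMBP fell by 0.94 (SE 0.22). The median was 0.28, the mean -0.12 and the camera direction up (adjusted p = 0.468). Of 11 alveolar and airway genes 2 rose and 1 fell, and adjusted over the list alone 2 rose and 2 fell. SFTPD (1.31, SE 0.31), a surfactant protein, and NAPSA (1.02, SE 0.22) rose, and the mucin MUC5AC fell by 1.08 (SE 0.09, adjusted p = 0.00012), with a median of 0.08, a mean of -0.10 and a camera direction of down (adjusted p = 0.709). Of 8 haematopoietic genes CD68, a lysosomal protein, rose by 0.41 (SE 0.07), and adjusted over the list alone 1 rose and 1 fell (median -0.12, mean -1.31, direction up, adjusted p = 0.554). Of 14 fibroblast and endothelial genes 1 rose and 2 fell, and adjusted over the list alone 2 rose and 3 fell. FAP rose by 1.96 (SE 0.45), and THY1 fell by 0.72 (SE 0.10) beside COL1A1, with a median of 0.04, a mean of 0.07 and a direction of down (adjusted p = 0.4). With limma on the deposited FPKM values, among features with a mean FPKM of at least 0.5, this list had a median of -0.66. Camera called it lower there (adjusted p = 0.000663), and after rescaling to one sum (0.00602), median scaling (0.0334) and quantile normalization (0.0448). That filter left out members such as FAP, so the members compared were not the same. Without the filter limma did not give this call. Without vector replicate 1 the haematopoietic list was called (adjusted p = 0.0389), and leaving out 1 library ended the calls of AMBP and FAP (any but vector replicate 1, up to 0.112 and 0.118), NAPSA (vector replicate 2 or any LOC401312 library, up to 0.0745) and SFTPD (any but LOC401312 replicate 2, up to 0.108).

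Of 11 kidney and cervical cell line genes, CDKN2A, which A549 cells are known to have deleted, fell, by either adjustment (adjusted p = 0.00717). It had 47, 18 and 17 counts in the vector libraries and 0 in the LOC401312 libraries, at least 28.7-fold lower against a floor of 3 counts over the group. The list's median was -0.18, with CDKN2A as fitted or at its bound (camera adjusted p = 0.249), and 0.11 in the deposited FPKM values. KRT13, the gene with the largest fall, showed a like distribution, with 338, 253 and 286 counts against 5, 0 and 0.

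By camera both lists on RNA quality were lower in LOC401312, while fry did not call the ribosomal list (adjusted p = 0.203). Of 13 mitochondrially encoded genes 4 fell, and 6 adjusted over the list alone. MT-ND3 fell by 0.51 (SE 0.08, adjusted p = 0.00281), MT-CO3 by 0.17 (SE 0.04, adjusted p = 0.0223) and MT-ND2 by 0.14 (SE 0.03, adjusted p = 0.0188). The median was -0.05 (camera adjusted p = 0.0207; adjusted p = 0.528 with an estimated correlation), and mitochondrial features held 9.46% to 10.07% of the counts in vector and 9.09% to 9.42% in LOC401312. Of 30 ribosomal protein genes 7 fell, and 9 adjusted over the list alone. RPL37A, on chromosome 2, fell by 0.52 (SE 0.07), RPS6, on chromosome 9, by 0.29 (SE 0.04) and RPS23 by 0.37 (SE 0.07). The median was -0.12 (camera adjusted p = 7.42e-05; adjusted p = 0.582 with an estimated correlation). In the deposited FPKM values the medians of the mitochondrial and ribosomal lists were 0.08 and 0, below the shift of 0.109, and with a length trend removed that of the mitochondrial list was 0 (adjusted p = 0.671). In the ribosomal list LOC401312 replicate 1 lay above vector replicate 1. This list had library medians of -0.044, 0.133 and 0.082 in vector and 0.03, -0.068 and -0.145 in LOC401312. Without LOC401312 replicates 2 and 3 its median was -0.03, while that of the mitochondrial list was -0.11. The mitochondrial list lost its call without vector replicate 1 (camera adjusted p = 0.057) or LOC401312 replicate 1 (0.0917), with total-count scaling (0.0612) and among features with a mean FPKM of at least 5 (0.202). Leaving out 1 library ended the calls of MT-ND2 (vector replicate 3 or any LOC401312 library, up to 0.0892), MT-CO3 (vector replicate 3 or LOC401312 replicate 1 or 2, up to 0.0902) and RPS23 (vector replicate 2 or 3 or LOC401312 replicate 3, up to 0.0642).

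Placental transcripts were present in 2 of the 3 LOC401312 libraries. CGA, the hormone alpha subunit, had 0.32, 0.89 and 0.39 CPM in the vector libraries and 0.35, 53.4 and 56.4 CPM in LOC401312 replicates 1, 2 and 3. The chorionic gonadotropin beta genes together had 1.21, 24.7 and 25.3 CPM in the LOC401312 libraries, the placental lactogen and growth hormone genes 0.18, 34.8 and 6.95 CPM, and the pregnancy-specific glycoproteins 1.29, 39.5 and 19.9 CPM. KISS1 and CGB8 had the same distribution. These genes were looked up after KISS1 and CGB8 had been seen among the largest rises, and members within each family share sequence, so families are given as sums.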

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

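The fits with total-count, median or RLE scaling of counts, a robust edgeR fit, a length trend or chromosome medians removed, plain FPKM and without LOC401312 replicates 2 and 3 were chosen after the result was seen. CPS1 and LOC401312 kept direction and call in all 27 settings that gave them a value, from 1.03 to 1.3 (adjusted p up to 0.00131) and from 7.48 to 13.12 (up to 4.69e-07). With each library left out in turn they ranged from 1.061 to 1.092 and from 12.224 to 13.125, genes higher from 393 to 963, genes lower from 439 to 1042 and gene lists called from 9 to 11, and 56 of 82 named genes and 8 of 11 lists kept their call without every library. Genes higher and lower numbered 108 and 118 without LOC401312 replicates 2 and 3, where fewer samples were fitted and the lone LOC401312 library is assumed to vary like the vector libraries. They numbered 135 and 66 at a change of at least 1, and 333 and 405 at an adjusted p under 0.01, as stricter thresholds must lower them. Genes lower fell to 577 with no filter, where more features share the adjustment, and to 570 with chromosome medians removed. DESeq2 called 1248 higher; the cause was not tested. Limma on FPKM, with its shift of 0.109 over genes with a mean FPKM of at least 5, called 2014 higher and 348 lower with pseudocount 0.1. It called 2030 and 353 with 1, 2004 and 346 with 0.01, 1618 and 288 at a mean FPKM of at least 5, 1238 and 214 without the trend, 2143 and 369 with robust, 180 lower with no filter and 511 lower after rescaling to one sum. Gene lists called were 1 with an estimated correlation, 7 at a mean FPKM of at least 5, 6 with limma and median scaling, 3 with quantile normalization and 4 in every other limma setting. The cause was not tested, and the 4 were not always the same lists. With limma and no filter the cholesterol list was called (median 0.124, camera adjusted p = 0.0114), the epithelial list kept its call and the ribosomal list lost it (0.256). RRM2 reversed to 0.052 (adjusted p = 0.482) with the median of its chromosome removed, and the mitochondrially encoded list to 0 (adjusted p = 0.695) with quantile normalization, neither past the threshold. The fibroblast and endothelial list, not called on counts, was called lower with limma on FPKM (median -0.66, camera adjusted p = 0.000663). There the filter of a mean FPKM of at least 0.5 left out members such as FAP. With the replicate number as a replicate block, genes higher and lower numbered 509 and 579 and 15 of 93 named genes lost their call, while all 26 lists, CPS1 and LOC401312 kept theirs. The deviations of libraries with the same number correlated at -0.27, 0.08 and -0.18, against -0.19 to 0.35 for libraries with different numbers. No pairing by number was seen, but with 3 libraries per group this cannot exclude one. At 60971105 to 73994619 counts per library, a count of 0, as for CDKN2A in LOC401312, allows up to 3 counts over the group.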

Other observations

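The tests over pathway terms, the placental genes, the vector-only genes, the chromosome 2 test over libraries and the NRF2 test over chromosomes were chosen only after the result was seen; the length and spread tests and the splits were set before theirs. Among KEGG terms, extracellular matrix receptor genes were higher, with 24 of 65 called higher and 7 lower (camera adjusted p = 0.000946; adjusted p = 0.594 with an estimated correlation). The laminin chain LAMA4 rose by 1.26 (SE 0.09), tenascin C, TNC, by 0.81 (SE 0.06) and the fibronectin receptor subunit ITGA5 by 0.41 (SE 0.04), while COL1A1 fell by 0.95. The genes of these terms were named after their values were seen. Lysosomal genes were higher, with 19 of 119 called higher and 3 lower (adjusted p = 0.0291; adjusted p = 0.594 with an estimated correlation): the cholesterol exporter NPC1 rose by 0.56 (SE 0.04) and the proteases CTSB and CTSS by 0.34 and 0.36, while CTSL fell by 0.43. VCAM1, an adhesion molecule induced through NF-kB, rose by 4.19 (SE 0.29, adjusted p = 3.39e-05). It was not among the 10 largest rises, which were limited to a mean FPKM of at least 1 in the higher group. The level of VCAM1 is not given here. Its KEGG term, NF-kappa B signalling, had 11 of 80 genes higher and 4 lower (camera adjusted p = 0.0127, or 0.594 with an estimated correlation). Ribosome genes were lower (1 higher and 32 lower of 132, adjusted p = 5.69e-10; adjusted p = 0.689 with an estimated correlation). Spliceosome genes were lower (0 higher and 21 lower of 130, adjusted p = 0.00721; adjusted p = 0.594 with an estimated correlation), with HNRNPA3, SF3B6, SNRPG and PCBP1 (-0.44, -0.43, -0.45 and -0.32) on chromosome 2 among the fallers. HSPA1B and HSPA1A (-0.56 and -0.49), on chromosome 6, fell as well, but are near-identical copies whose separate counts are uncertain. In all, 13 of 301 KEGG and 55 of 1348 Reactome terms were called, and 0 of either with an estimated correlation.

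Several genes were nearly confined to the vector libraries, among them CDKN2A, which A549 cells are known to have deleted, with 47, 18 and 17 counts against 0, and the origin of these transcripts was not tested. TMPRSS4, a membrane protease, had 161, 34 and 14 counts in vector and 0 in LOC401312, at least 73.2-fold lower against 3 counts over the group. KRT17 had 67, 137 and 71 counts against 0, 8 and 0. The metalloproteinase inhibitor TIMP3 and the cadherin CDH11 were lower but still present in LOC401312: TIMP3 had 347, 316 and 315 counts against 17, 49 and 44, and CDH11 had 221, 144 and 175 against 38, 29 and 27. These genes were chosen after their values were seen.

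The real split of the 6 libraries called 1710 genes, as 1 of 10 splits, and the highest of the others called 1; 10 splits are too few for a share under 0.05.

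Genes of chromosome 2 had a median log2 change of -0.233. A transcript length trend was argued against, since the median was -0.25 with that trend removed, and so was an effect of part of the libraries, since all 6 lay on their group's side. The spread of the changes was 1.12 times that of the other chromosomes, as one shift of the whole chromosome requires, and a lower number of chromosome 2 copies in the LOC401312 cells is a candidate explanation. DNA copy number was not analysed here, and whether such a difference arose with the introduced transcript or between separately made cell populations stays open. CPS1 rose against this shift.

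Placental transcripts stood out in LOC401312 replicates 2 and 3. A response to the introduced transcript in all 3 libraries was argued against, since 5 of 14 placental families lay above every vector library in replicate 1, whose STEAP1B level was 1342 CPM against 1356 and 1353 CPM in replicates 2 and 3. A single placental source in one makeup was argued against by the ratio of replicate 2 to replicate 3, which differed 7.04 times between families, from 5.01 (95% interval 4.53 to 5.54) for the placental lactogen and growth hormone genes to 0.947 (0.9 to 0.99) for CGA and 0.712 (0.4 to 1.24) for PAGE4, which had few counts. RNA of placental cells may still have entered both libraries, from different sources: 11 of 14 families and 1 of 27 other placental genes, 12 of 41, were at least 3 times higher in both than elsewhere. The 14 were listed after their counts had been seen, and of the 27, KRT7, PAPPA and PEG10 are abundant in A549 and would hide a small share, but TAC3, CRH and DLK1, near 0 in vector, and IGF2 were not raised in both libraries either, so without a measured placental profile this cannot be told apart from activation of some placental genes in part of the cells.

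NRF2 targets were lower in LOC401312, with 18 of 28 falling, and the lists on RNA quality had negative medians too (ribosomal -0.12, mitochondrial -0.05). Without LOC401312 replicates 2 and 3 the medians were -0.23 for the NRF2 list, -0.03 for the ribosomal list and -0.11 for the mitochondrial list. RNA quality as an explanation was not tested and stays open. A transcript length trend was argued against, since the median was -0.21 with that trend removed and 18 members were still called lower. Chromosome shifts were argued against, since the 25 members outside chromosomes 2, 9 and 12 had a median of -0.24. A change in NRF2 activity with the introduced transcript, or a difference between the cells of the groups that has nothing to do with it, may each account for this and cannot be separated by this design, and the list was not called with an estimated correlation (adjusted p = 0.153).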
